A study of Mus musculus with 2 samples.

How the data were processed

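Chromatin from the limb of mouse embryos (strain B6NCrl) at embryonic day 13.5, from pools of both sexes, was immunoprecipitated with an antibody against histone H3 acetylated at lysine 27 (H3K27ac) and sequenced (ChIP-seq). Per the labels there are 2 biological replicates in 1 group. Replicate 1 combines 2 technical replicates, sequenced on different Illumina instruments, and replicate 2 has 1. There is no other group, stage or tissue, so the comparison between samples is between the replicates, and all others are between parts of the genome within a list.

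The authors deposited 4 peak lists on the mouse assembly mm10. Each replicate's list was derived by the authors from that replicate's filtered alignments and its own control, the pooled list from both replicates and both controls, and the replicated list from both replicates' lists and the pooled list. Per the file headers and column order, the seventh column is a ratio, the authors' fold enrichment over the control, and the deposited columns after it are the −log10 p and the −log10 q of each peak. The last deposited column is the offset of the summit from the start of the peak. The aligner, the peak caller, its threshold and the rule that makes a peak replicated are not given in the sources used here. Fold values come from the authors' caller and depend on depth, so they were ranked and compared within a list and across lists only where stated.

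The lists give no read totals, so the sequencing depth of each replicate is unknown. Many fold values of each list fall on a regular spacing (52.1% of peaks in replicate 2, 54.9% in replicate 1, 57.5% in the replicated and 58.9% in the pooled list), which gives a background read pileup for these peaks if a summit's pileup is a whole number. It scales with the fragment length, which is not given in the sources used here, as well as with depth. This pileup was 2.33 reads for replicate 1, 2.94 for replicate 2 and 5.12 for the pooled and replicated lists. The −log10 p of a Poisson count with this background was set against the deposited one at the most common pairs of fold and p. In each list it matched for 6 of the 6 most common pairs. Peaks on chromosomes 1 to 19, X and Y were used, and overlapping peaks within a list would have been merged (there were 0). Peaks on scaffolds with no chromosome position were left out, since shuffles and gene distances are not defined there. Positions are counted from 1, with both ends included.

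Genes were the 21938 protein-coding genes of the GENCODE vM21 basic annotation on GRCm38, the sequence of mm10. A promoter was the sequence within 1 kb of the transcription start site (TSS) of any protein-coding transcript of a gene in this basic set. A region was distal when it lay over 1 kb from every TSS of the annotation, including those of genes that are not protein-coding. Each region was placed by its summit in a promoter, exon, intron or intergenic sequence. A gene's regulatory domain ran from 5 kb upstream to 1 kb downstream of the 5' end of its gene record, which for some genes lies upstream of all basic transcripts, and was extended to the neighbouring genes' domains, by at most 1 Mb. Extended domains of neighbouring genes overlap, so a distal region can count for more than 1 gene. Regions within 10 kb of each other were joined into clusters, ranked by acetylated bases. The number of shared regions, the annotation and the regulatory landscapes were compared with 100 seeded shuffles of the regions within their chromosomes, in a one-sided permutation test whose smallest p is 0.0099. For the annotation the smaller of both tails was taken after the shares were seen, so its p is smaller than a two-sided one.

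The gene lists, motifs, tests and alternatives were chosen before the data were examined, except where said otherwise. The 17 gene lists were limb transcription factors, limb signalling, cartilage, bone, tendon and connective tissue, skeletal muscle, surface ectoderm, endothelium, erythroid cells, macrophages, Schwann cells and melanocytes, neurons, hepatocytes, cardiomyocytes, germline and pluripotency, housekeeping genes and olfactory receptors. The share of a list's promoters with a region was compared with all other protein-coding genes in a two-sided Fisher's exact test, with Wilson 95% intervals that cover counting error only. The median of the distal acetylated bases in a list's domains was compared with 10000 random lists matched on domain length, in a two-sided permutation test. Motifs were 21 consensus sequences, counted within 100 bp of distal summits and in windows outside all lists matched on GC content in 2% bins, with a two-sided Fisher's exact test. Each p was adjusted by the Benjamini-Hochberg method over the lists or motifs. Genes and regions are not replicates, so every p describes these libraries and not other embryos.

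The genes named were, from each list, the 3 with the highest promoter fold, the first 2 by name without a promoter region and the 2 with most distal acetylated bases. All Hox genes, 12 further limb and control genes (Shh, Lmbr1, Tbx5, Tbx4, Pitx1, Fgf8, Sox9, Col2a1, Gdf5, Myod1, Krt14 and Alb), the genes of the 20 clusters with most acetylated bases, and the 10 strongest regions of each replicate that share no base with the other were named as well.

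Alternatives were the pooled list, each replicate's list in place of the replicated one (leaving out the other replicate), a fold of at least 4, a −log10 q of at least 2, a reciprocal overlap of at least 50%, a summit inside the other region, lists of equal length, promoter windows of 500 bp and 2 kb, random lists matched on the CpG content of promoters, a window of 100 kb on either side of the TSS in place of the domain, joining within 5 kb and 20 kb, ranking clusters by summed fold, motif windows of 200 bp on either side, distal regions over 5 kb from a TSS, and windows shuffled with their dinucleotides kept. The use of replicated regions that touch a peak of both replicates was added after the data were seen. The replicate overlap, the promoter lists, the domain lists and the motif counts were tested on simulated data, and the other calculations were not. A planted overlap of 40.2% was found as 40.9%, all 40 planted promoter lists and all 20 planted domain lists were found, and 7.00% of 200 null promoter lists and 2.50% of null domain lists had an unadjusted exact or permutation p under 0.05. A motif planted in 5% of windows raised its share by 5.69 points. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9, and samtools 1.23.1, were used.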

Results

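H3K27ac, a histone mark of active promoters and enhancers, was mapped in the limb of mouse embryos at day 13.5, when the skeleton is being laid down as cartilage and the digits take shape. The data are 1 group of 2 biological replicates. Replicate 1 had 109285 peaks, which covered 52.1 Mb, or 1.97% of the genome (median width 287 bp, median fold enrichment 3.69). Replicate 2 had 57346 peaks over 24.4 Mb, or 0.920% (median width 274 bp, median fold 3.30). The pooled list held 117726 peaks over 57.8 Mb, and the replicated list held 47757 peaks over 40.2 Mb, or 1.52% of the genome, with a median width of 594 bp and a median fold of 4.17. Every one of the 47757 replicated peaks stood in the pooled list with identical values. The 47751 replicated peaks on chromosomes, here called regions, are the acetylated regions described unless another list is named. Sequencing depth is unknown, and with 2 samples of 1 group no test between samples was possible.

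The first question was how far the replicates agree. The strongest acetylated regions were found in both replicates, and the unshared ones were weak and narrow. Of the 57342 replicate 2 regions on chromosomes, 73.6% shared at least 1 bp with a replicate 1 region, against 4.11% for shuffled regions. Of the 109276 replicate 1 regions, 31.5% were shared, against 2.16%. In the decile of highest deposited −log10 p, 98.7% of replicate 1 regions and 100% of replicate 2 regions were shared. In the lowest decile 8.40% and 51.7% were shared. The unshared replicate 1 regions had a median fold of 3.49 and a width of 238 bp, and 13 of 74908 reached a fold of 10. The unshared replicate 2 regions had a median fold of 3.05 and a width of 202 bp, and 0 of 15122 reached 10.

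**Figure D1:**
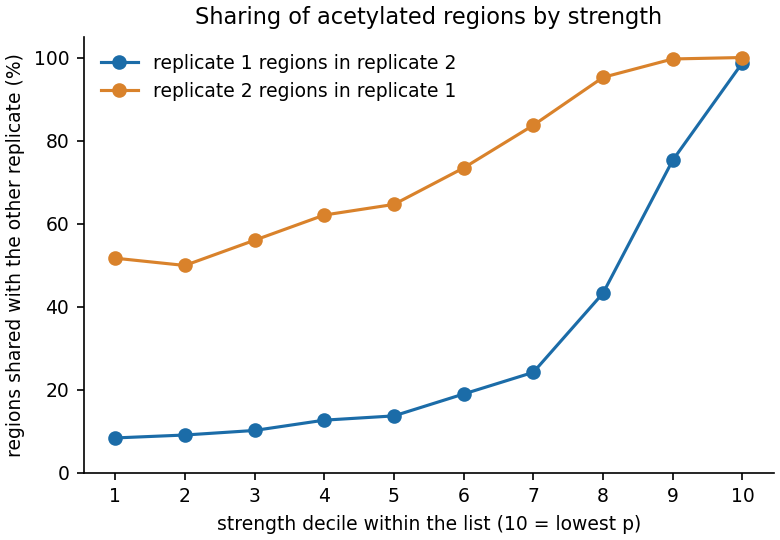
Percent of each replicate's regions that share at least 1 bp with the other replicate's list (vertical axis). Deciles of the deposited −log10 p within the replicate's own list run from weakest to strongest (horizontal axis). The share rises from 8.40% to 98.7% in replicate 1 and from 51.7% to 100% in replicate 2.

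The strongest regions found in a single replicate lay mostly at promoters in replicate 1 (8 of 10 within 1 kb of a TSS) and mostly away from them in replicate 2 (3 of 10). In replicate 1 they were nearest to Nsmce1 (fold 13.8), Ice1 (12.3), Ocrl (12), Phldb2, Rasgef1b and Phf6 (10.8 each), Matn3, Ctso and Scoc (10.5 each) and Sgo2a (10.2). Matn3 encodes a matrix protein of cartilage. In replicate 2 they were nearest to Snrnp25 and Actrt2 (5.84 each), Zfp532 and Magel2 (5.59 each), Scfd2 (5.40), Atf7ip (5.37), Serpine2, F2rl1 and Eed (5.33 each) and Xpot (5.08). All 20 were in the replicated list, so that list is not the intersection of the replicates.

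Both shared percentages had a one-sided permutation p of 0.0099, the smallest that 100 shuffles can give, and the Jaccard index of covered bases was 0.338 against 0.00708. Over the 42220 shared replicate 2 regions, Spearman's rho of fold between replicates was 0.581 (95% bootstrap interval 0.575 to 0.589), and the fold was higher in replicate 1 at 92.2% of them (median ratio 1.72). This correlation is across regions, which are not independent replicates. Each replicate 2 region was paired with the overlapping replicate 1 region of highest fold. The 34368 shared replicate 1 regions could therefore each serve more than 1 pair. Such a pairing tends to raise the ratio and the 92.2% in favour of replicate 1, by an amount that was not measured. A reciprocal overlap of at least 50% lowered the shared percentages to 15.9% for replicate 1 and 30.3% for replicate 2, and among equally long lists of the strongest regions 50.7% of replicate 1's were shared. Of the replicated regions, 67.9% touched a peak of both replicates.

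The next question was where in the genome the mark lies. Acetylated regions were concentrated at promoters and scarce in intergenic sequence. Promoters held 26.7% of regions (12757), 12.2 times the 2.19% of shuffled regions, and 10521 of 21938 protein-coding genes (48.0%) had a region at a promoter. Distal regions numbered 32416 and were narrower and weaker (median 534 bp, fold 3.79) than the 13354 regions that touched a promoter window (773 bp, fold 6.53). Exons held 4.52% of summits against 3.70%, and intergenic sequence 25.6% against 50.8%, each with a permutation p of 0.0099, the smallest possible. Introns held 43.2% against 43.3% (permutation p = 0.238), but the direction depended on the setting. It lay above the shuffled share in the pooled list (50.8%), in replicate 1's list (50.7%) and with a promoter window of 500 bp (44.9 against 43.9%), and below it at fold 4 or more (34.2%), for regions that touch a peak of both replicates (38.7%) and with a window of 2 kb (41.3 against 42.2%). The share at promoters was 15.6% in replicate 1's longer list and 25.5% in replicate 2's.

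The gene lists asked which cell types' genes carry the mark. Promoters of limb patterning and cartilage genes were acetylated far more often than those of other genes. Of the 39 limb transcription factors, 36 had a promoter region (92.3%, Wilson 95% interval 79.7 to 97.3%), against 47.9% of other genes. The strongest were Gli3, a hedgehog effector that patterns the digits (chromosome 13, 15463235 to 15730026; fold 42.3, and 45.5 and 28.4 in the replicates), Prrx1, a factor of limb mesenchyme (chromosome 1, 163245119 to 163313710; fold 41.5, and 44.5 and 23.9), and Hoxa10 (fold 30.7). Alx3 and Sall3 had no promoter region. The factors that mark forelimb and hindlimb identity were all acetylated, Tbx5 with fold 18.8, Tbx4 with 12.8 and Pitx1 with 15.4. Of the 22 cartilage genes, 20 had a promoter region (90.9%, interval 72 to 97%), led by Pth1r, a receptor that restrains chondrocyte maturation (fold 18.9), Sox9, the master regulator of chondrocytes (17.2, and 19.2 and 12.1 in the replicates), and Col2a1, the main cartilage collagen (16.0, and 18.3 and 10.7). Ihh, the growth plate signal, and Ucma had none. Gdf5, a signal of the forming joints, had a fold of 15.8.

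Connective tissue genes were also acetylated, with 13 of 15 genes of tendon and connective tissue (86.7%, interval 62.1 to 96.3%). The strongest members of the list as chosen were Tcf4 (fold 37.7), Tcf7l2 (34.6) and the collagen gene Col3a1 (19.4). Tcf4 and Tcf7l2 are separate genes, and whether Tcf4 marks connective tissue was not examined here. The tendon genes Thbs4 and Tnmd had no promoter region. All 16 housekeeping genes had one, led by Actb (44.4), Ywhaz (31.7) and Eef1a1 (27.1). Of the 30 limb signalling genes, 21 had one (70.0%, interval 52.1 to 83.3%), led by the hedgehog receptor gene Ptch1 (32), Wnt5a (29.7), a ligand of limb outgrowth, and Spry2 (27.6), a feedback inhibitor of growth factor signalling. Aldh1a2, Fgf17, Shh and Fgf8 had none. Adjusted exact p were 3.99e-08 for limb transcription factors, 1.37e-04 for cartilage, 0.00662 for tendon and connective tissue, 4.41e-05 for housekeeping and 0.0293 for limb signalling. The lists were higher in both replicates, but limb signalling missed the threshold in replicate 1's list (exact p = 0.0651), at fold 4 or more (0.0837) and against genes of like promoter CpG content (permutation p = 0.663).

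Promoters of neuron, macrophage, germline, hepatocyte, erythroid and olfactory receptor genes were acetylated less often than those of other genes in the replicated list. Neuron genes (0 of 16, interval 0 to 19.4%, Ascl1 and Dlx1 among them), macrophage genes (0 of 13, interval 0 to 22.8%, Aif1 and C1qa among them) and germline and pluripotency genes (0 of 9, interval 0 to 29.9%, Dazl and Ddx4 among them) had no promoter region in the replicated list. Replicate 1's list had 2 macrophage genes (15.4%), Aif1 (3.6) among them, and 1 neuron gene (6.25%), Ascl1 (fold 3), and replicate 2's had 1 germline gene (11.1%), Dazl (4.06). Hepatocyte genes had 1 of 14 (Foxa3, fold 3.20), with none at Alb, Afp or Ahsg. Erythroid genes had 3 of 16 (Ank1 with fold 4.08, Nfe2 with 3.92 and Klf1 with 3.65), with none at Alas2 or Epb42. Olfactory receptor genes had 2 of 1135, or 0.176%, against 50.6% of other genes (Olfr1342 with fold 3.92 and Olfr156 with 2.59), with none at Olfr1 or Olfr10. Klf1 and Olfr1342 had no promoter region in replicate 2's list, and Foxa3 and Olfr156 had none in replicate 1's. Adjusted exact p were 1.37e-04 for neurons, 7.80e-04 for macrophages, 0.00781 for germline, 0.00493 for hepatocytes and 0.0354 for erythroid cells, and for olfactory receptors the p was too small to be represented. Shares were lower in both replicates, but erythroid and germline genes missed the threshold in replicate 2's list (exact p = 0.0580 each), erythroid genes in the pooled list (37.5%, exact p = 0.272) and hepatocyte genes with a promoter window of 2 kb (21.4%, exact p = 0.0898). Against genes of like promoter CpG content the permutation p was 1 for erythroid, 0.361 for macrophage and 0.390 for hepatocyte genes.

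Genes of other limb cell types and of the heart passed no threshold in the promoter test. Skeletal muscle had 8 of 20 (40%, adjusted exact p = 0.578), but 65.0% in replicate 1's list (exact p = 0.487) and 70.0% in the pooled one (exact p = 0.316), both above other genes, with Six4 (fold 13.6), Mef2c and Six1 (9.31 each) strongest and none at Acta1 or Actc1, which encode actins of differentiated muscle. Myod1, the myogenic regulator, had a fold of 3.27 and was found in replicate 1 (3.90) but not in replicate 2's list. Bone had 6 of 12 (exact p = 1), with Col1a1 (17.1), Col1a2 (14.6) and the osteoblast regulator Runx2 (8.84), and none at Alpl or Bglap, genes of mineralising osteoblasts. Surface ectoderm had 5 of 17 (exact p = 0.211), with Tfap2a (11.3), Grhl2 (4.57) and Perp (3.66), and none at Cdh1, Dlx3 or Krt14. Endothelium had 6 of 14 (42.9%, exact p = 0.842), but 78.6% in the pooled list (exact p = 0.164), with Erg (14.5), Pecam1 and Tek (4.08 each), and none at Cdh5 or Cldn5. Schwann cells and melanocytes had 4 of 12 (exact p = 0.476), with Mpz (6.70), Erbb3 (5.06) and S100b (3.92), and none at Cdh19 or Dct. Cardiomyocytes had 4 of 14 (exact p = 0.241), with Myl4 (13.2), Myl3 (3.76) and Tnnt2 (3.43), and none at Gata4 or Myh6. Of the genes named here with a promoter region, Grhl2, Pecam1, Myl3 and Tnnt2 also had none in replicate 2's list. Ectoderm and cardiomyocyte genes were lower than other genes in replicate 2's list (exact p = 0.0433 each) and at fold 4 or more (11.8%, exact p = 0.0182, and 7.14%, exact p = 0.0112), and ectoderm genes also for regions that touch a peak of both replicates (11.8%, exact p = 0.0101). In replicate 1's and the pooled list ectoderm genes were near other genes (47.1 against 53.5%, exact p = 0.769, and 52.9 against 55.2%, exact p = 1).

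**Figure D2:**
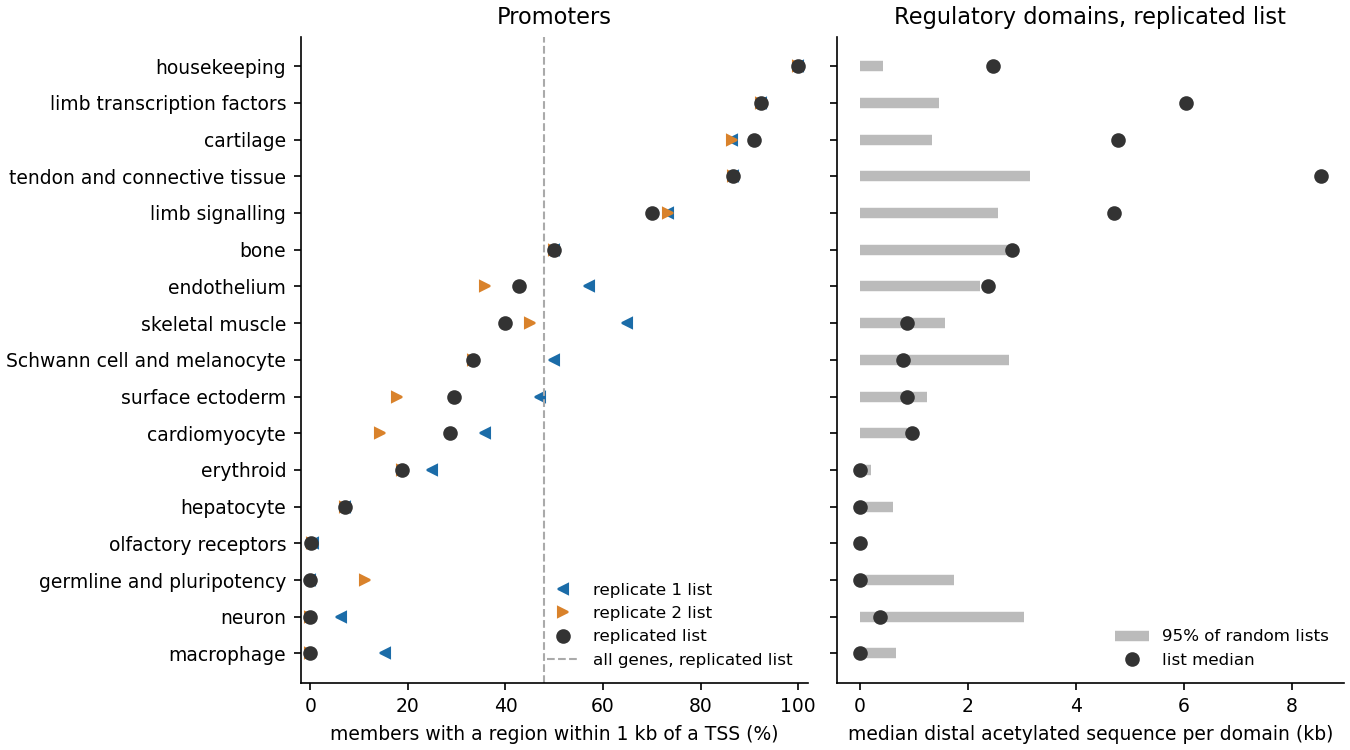
Left, percent of each gene list's promoters with an acetylated region, in the replicated list and in each replicate, with all genes as a dashed line, and right, median distal acetylated sequence per regulatory domain (kb, replicated list), with the range of 95% of random lists in grey. Limb transcription factors (92.3%), cartilage (90.9%) and housekeeping genes (100%) lie far above the 48.0% of all genes, and neuron, macrophage and germline genes lie at 0% in the replicated list (up to 6.25%, 15.4% and 11.1% in a replicate's list).

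Distal acetylation was higher around the same limb, cartilage, connective tissue and housekeeping genes. The median limb transcription factor had 6040 acetylated distal bases in its domain, against 387 in random lists, the median cartilage gene 4788 against 154, the median tendon and connective tissue gene 8533 against 656, the median limb signalling gene 4713 against 817 and the median housekeeping gene 2473 against 0. Lmx1b, the dorsal identity factor (chromosome 2, 33560965 to 33640511), had 54911 bases in 47 regions, and Gli3 42344 bases in 68. Sox9 (chromosome 11, 112782224 to 112787760) had 56579 bases in 84 regions, Sox6, its partner in cartilage, 35645, and Col2a1 (chromosome 15, 97975602 to 98004695) 31107 bases in 29. Tcf7l2 had 62144 bases, Tcf4 56647, Wnt5a 43862 and Cyp26b1, which degrades retinoic acid, 30492. Among housekeeping genes Hprt had 20876 and Rplp0 15003. Adjusted permutation p were 8.50e-04 for limb transcription factors, cartilage, tendon and housekeeping, from unadjusted p that are the smallest the 10000 random lists can give, and 0.00612 for limb signalling. These lists were higher in both replicates, but limb signalling missed the threshold with a window of 100 kb on either side of the TSS (2330 against 729 bases, permutation p = 0.0601).

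Single genes of the other lists had distal regions, some of them without a promoter region. Since neighbouring domains overlap and differ in length, these bases are not assigned to the named gene alone. The endothelial cadherin gene Cdh5, without a promoter region, had 27192 distal bases in a domain of 1064 kb. Erg, with a promoter region, had 22708 in a domain of 439 kb. The endothelial list's median of 2379 against 318 missed the threshold (adjusted permutation p = 0.101, but 0.0340 in replicate 1's list and 0.0486 in the pooled one). Mitf, the melanocyte regulator, had 22430 and Dct 6428 (list median 794 against 451, permutation p = 0.937). The ectodermal regulators Grhl3 (promoter fold 2.61, none in replicate 2's list) and Trp63 (no promoter region) had 9007 and 8368 (874 against 0, permutation p = 0.258). Ptprc had 12365 and Csf1r 5741, although the median macrophage gene had 0 (permutation p = 1). Bone, with Col1a1 at 31398 and Runx2 at 18291, had a median of 2824 against 459 (permutation p = 0.110). Muscle, with Mef2c at 7248 and Six1 at 6608, had 872 against 288 (permutation p = 0.486), cardiomyocytes, with Myl3 at 4775 and Nkx2-5 at 1846, 961 against 0 (permutation p = 0.101), and neurons, with Slc17a6 at 4767 and Neurod6 at 3077, 372 against 644 (permutation p = 0.937). The medians were 0 for erythroid (Gypa with 3957, Alas2 with 529), hepatocyte (Apoa1 with 9505, Foxa3 with 3913), germline (Nanog with 7306, Dazl with 1713) and olfactory receptor genes (Olfr267 with 20622, Olfr159 with 5534), each with a permutation p of 1. In replicate 1's list the olfactory receptor median was also 0 but lay below the 184 bases of random lists (permutation p = 0.00340), as in the pooled list and with a window of 100 kb.

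The Hox clusters, which pattern the limb from body wall to digits, were acetylated unevenly. The strongest promoter regions lay in HoxA and HoxD, and those of HoxC and HoxB were few and weak. In HoxA, 8 of 11 genes had a promoter region, with Hoxa10 at fold 30.7, Hoxa11 at 25, Hoxa9 at 23.5, Hoxa3 at 19.3 (at an upstream start site), Hoxa13 at 18, Hoxa7 at 14.5, Hoxa1 at 3.93 and Hoxa6 at 3.27. The replicated list had none at Hoxa2, Hoxa4 or Hoxa5, although Hoxa4 had one in both replicates' lists (3.6 and 3.3) and Hoxa5 in replicate 1's (2.90). Hoxa1 had none in replicate 2's list. In HoxD, 7 of 9 had one, with Hoxd11 at 20.1, Hoxd12 at 18, Hoxd13 at 17.3, Hoxd10 at 14.7, Hoxd8 at 10.6, Hoxd9 at 8.24 and Hoxd3 at 4.74, and none at Hoxd1 or at the transcript starts of Hoxd4. The gene record of Hoxd4 begins at 74711929, 2 bp from the start of Hoxd3, so the region at Hoxd3 lies there too. In HoxC, 4 of 9 had one, Hoxc10 (5.80), Hoxc5 (5.39), Hoxc11 (4.43) and Hoxc13 (3.76), and Hoxc4, Hoxc6, Hoxc8, Hoxc9 and Hoxc12 had none in the replicated list. Each replicate's own list had 5 HoxC promoters. In HoxB, 1 of 10 had one, Hoxb2 (4.74), and Hoxb1, Hoxb3, Hoxb4, Hoxb5, Hoxb6, Hoxb7, Hoxb8, Hoxb9 and Hoxb13 had none. Replicate 1's list had 4 HoxB promoters, the others being Hoxb4 (3), Hoxb7 (3.6) and Hoxb9 (4.20). Among paralogues 9 to 13, which act in limb development, 12 of 16 had a region, with 4 of 4 in HoxA, 5 of 5 in HoxD, 3 of 5 in HoxC and 0 of 2 in HoxB. Of all 39 Hox genes, 20 had a promoter region in the replicated list, 26 in replicate 1's and 21 in replicate 2's.

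The gene deserts beside HoxD hold its limb enhancers, and the centromeric one, known for its role in digits, was the more acetylated. Between Atp5g3 and Evx2 (chromosome 2, 73911327 to 74652990) 46 regions covered 32.1 kb, 2.39 times the shuffled mean. Between Hoxd1 and Hnrnpa3 (74765143 to 75659260) 24 regions covered 15.8 kb, 1.03 times. Regions at promoters were not removed from these windows. The strongest region of the second window (75657150 to 75659002, fold 27.3) lies beside the start of Hnrnpa3. A region of fold 13.9 (73910416 to 73911832) crosses the edge of the first at Atp5g3. At its other edge the first window takes in regions from 74648773 to 74652338, which are also counted in the joined HoxD cluster below. The sequence between Hoxa13 and Hibadh (chromosome 6, 52260881 to 52546227) had 4 regions over 7.55 kb, 1.54 times. Along Lmbr1 (chromosome 5, 29229802 to 29378390), a neighbour of Shh, the promoter had a region of fold 5.23 and the lists used here held no intronic region. The permutation p was 0.0099 for the centromeric desert, the smallest possible (0.0198 in replicate 2, with 2.07 times, and 0.0099 in replicate 1, with 2.38 times), and 0.376 for the telomeric one, and the difference between them was not tested. For the HoxA flank the permutation p was 0.158, but 0.0396 in replicate 1 (1.83 times) and 0.0198 in replicate 2 (2.65 times). The shuffles place regions independently, whereas 10346 of the 21836 clusters described below held more than 1 region. Shuffled totals therefore vary less than those of clustered regions would, and these permutation p are likely too small.

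**Figure D3:**
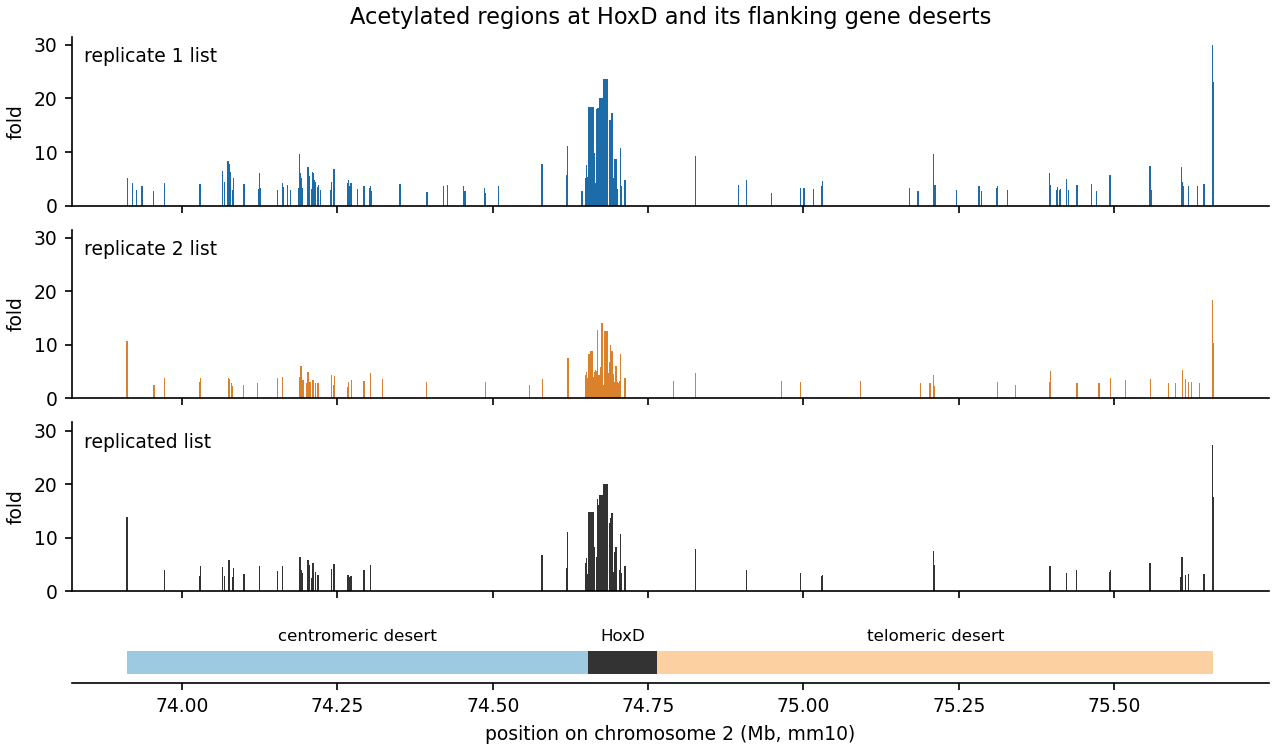
Acetylated regions across the HoxD cluster and its flanking gene deserts on chromosome 2 (horizontal axis, position in Mb; vertical axis, fold enrichment within each list) in replicate 1, replicate 2 and the replicated list, with regions drawn at least 2 kb wide. The centromeric desert holds 46 replicated regions and the telomeric one 24.

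Joining regions within 10 kb gave 21836 clusters, of which 10346 held more than 1 region and 99 held over 20 kb of acetylated sequence. The cluster with most acetylated bases, which also holds the imprinted RNA gene H19, covered Lsp1, Mrpl23 and Tnnt3 (chromosome 7, 142453938 to 142612768; 94.9 kb in 49 regions, and 97.6 and 63.6 kb in the replicates). The second covered the imprinted gene Mest, Cep41 and a run of carboxypeptidase genes (chromosome 6, 30568199 to 30748250; 77.6 kb). The third covered Ski, Morn1, Rer1 and Faap20 (chromosome 4, 155085616 to 155251108; 58.4 kb). Those at Pigc (57 kb), Nfix with Nacc1 and Lyl1 (56.3 kb), 95015 bp from the TSS of Fancc (52.4 kb) and at Sept9 (50.9 kb) came next. HoxA (52208236 to 52276283; 49.9 kb) and HoxD with Evx2 (74648773 to 74712586; 47.4 kb) ranked 8 and 9. The others among the top 20 lay at Actn4 (43.9 kb), near Wwp2 (43.4), and at Fignl1 (42.9), Notch2 (42.5), Dusp7 (41.2), Cdc6 with Rara (38.7), Hhat with Sertad4 (38.4), near Dnm3 (37.7), and at Capzb (37.1), Col2a1 with Tmem106c (36.9) and Vgll4 (36.6). Together the top 20 held 2.45% of acetylated bases. In replicate 1's list 10 of these were among its top 20, in replicate 2's 15, and replicate 1's list gave 32831 clusters.

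The distal regions were searched for the sites of transcription factor families, in 32416 windows of 200 bp (GC content 51.0% in windows and background). The E-box CAGCTG of basic helix-loop-helix factors showed the most significant enrichment, with 16.3% of windows against 12.5% (1.31 times). RUNX sites (TGTGGTTW, 2.19 against 1.69%, 1.30 times), forkhead sites (TGTTTAC, 2.64 against 2.06%, 1.28 times), homeodomain sites (TAATTA, 2.69 against 2.30%), TEAD sites (GGAATGY, 6.12 against 5.23%) and LEF/TCF sites (CTTTGAW, 6.72 against 5.77%), each 1.17 times, and SOX sites (ACAAWGG, 7.74 against 6.87%, 1.13 times) were also enriched. Adjusted exact p ran from 2.52e-42 for CAGCTG to 0.00447 for the homeodomain site, and these 7 were enriched in both replicates. LEF/TCF sites fell to 0.906 times when the background was the same windows shuffled with dinucleotides kept, and homeodomain sites missed the threshold at fold 4 or more (exact p = 0.0774). For regions that touch a peak of both replicates, homeodomain (1.13 times, exact p = 0.121) and TEAD sites (1.08 times, exact p = 0.112) missed it too. Sites of the liver factor HNF4 were enriched (0.339 against 0.219%, 1.55 times, exact p = 0.0119), but not in replicate 1's list (1.17 times, exact p = 0.131) or replicate 2's (1.26 times, exact p = 0.123). HNF4 also missed the threshold at fold 4 or more (1.07 times, exact p = 0.977) and for regions that touch a peak of both replicates (1.15 times, exact p = 0.565). So it did with wider windows, over 5 kb from a TSS and against shuffled windows, and it passed in the pooled list (1.23 times, exact p = 0.0201).

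The other 13 motifs passed no threshold in the replicated list. They were AP-1 (1.08 times background), the TWIST1 E-box CAGATG (1.01), HOX13 (0.949), HOX9-11 (1.11), MEIS/PBX (0.992), MEF2 (1.16), GATA (0.913), ETS (1.13), GLI (1.00), CTCF (0.782), REST (0.881), GRHL (0.714) and P53/P63 (0.5, from 1 against 2 windows). In each replicate's list MEF2 and HOX9-11 sites were enriched, MEF2 at 1.55 times in replicate 1 and 1.89 in replicate 2 and HOX9-11 at 1.18 and 1.17, and CTCF (0.791 and 0.753), HOX13 (0.929 and 0.931) and REST sites (0.772 and 0.689) were depleted, with adjusted exact p of at most 0.0325. In replicate 1's list AP-1 (1.1) and the TWIST1 E-box (1.02) were enriched as well. CTCF sites were depleted further at fold 4 or more (0.438 times, exact p = 5.13e-04) and for regions that touch a peak of both replicates (0.520 times, exact p = 5.97e-04). Against windows shuffled with dinucleotides kept, AP-1 turned to 0.794 and HOX13 to 1.53. Motif matches do not tell members of a family apart.

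**Figure D4:**
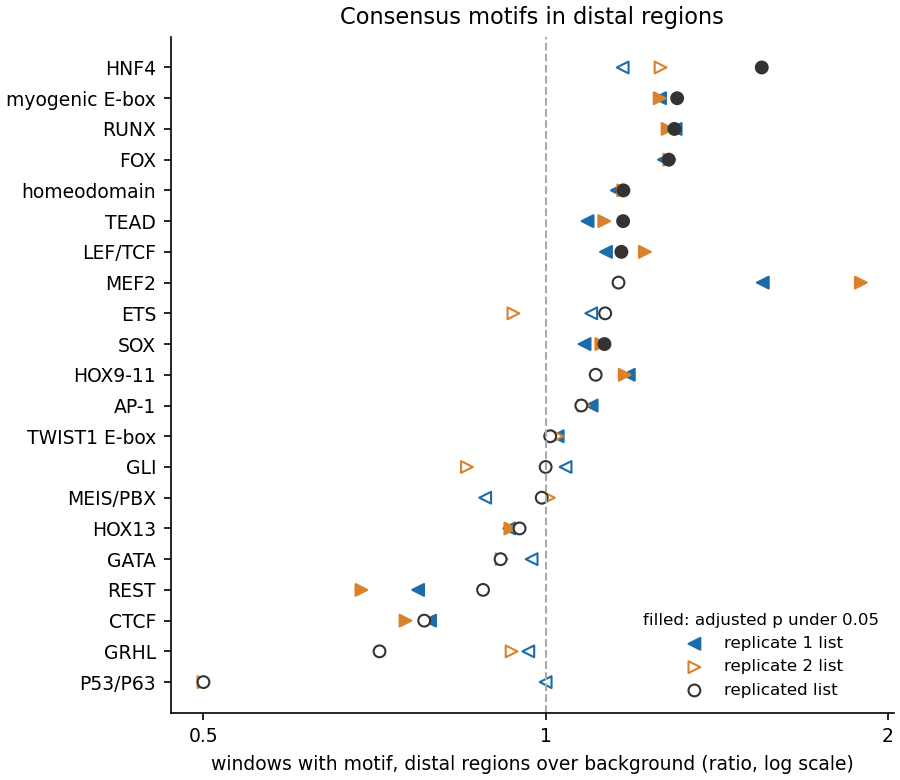
Ratio of the percent of distal windows with each motif to that of windows matched on GC content (horizontal axis, log scale; filled symbols have an adjusted exact p under 0.05), for the 21 motifs in the replicated list and in each replicate. In the replicated list HNF4 lies at 1.55, CAGCTG at 1.31, RUNX at 1.30 and forkhead at 1.28, and CTCF at 0.782. HNF4 missed the threshold in each replicate's list.

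Chromosomes differed in the density of acetylated regions, and the X chromosome stood apart. It carried 698 regions, or 4.27 per Mb, against 19.6 per Mb on the autosomes (47050 regions), a ratio of 0.217. Chromosome 11 was densest (30.3 per Mb) and chromosome 3 the sparsest autosome (14.6 per Mb), and the Y chromosome had 3 regions. Of 948 protein-coding genes on the X, 297 (31.3%) had a promoter region, against 10222 of 20807 (49.1%) on autosomes. Among promoters with an observed over expected CpG ratio of at least 0.6 these shares were 64.8% and 77.7%, with a median fold of 6.61 and 8.99. The gap was wider away from promoters, with 291 distal regions on the X and 32124 on autosomes. The X to autosome ratio was 0.188 in replicate 1 and 0.181 in replicate 2.

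**Figure D5:**
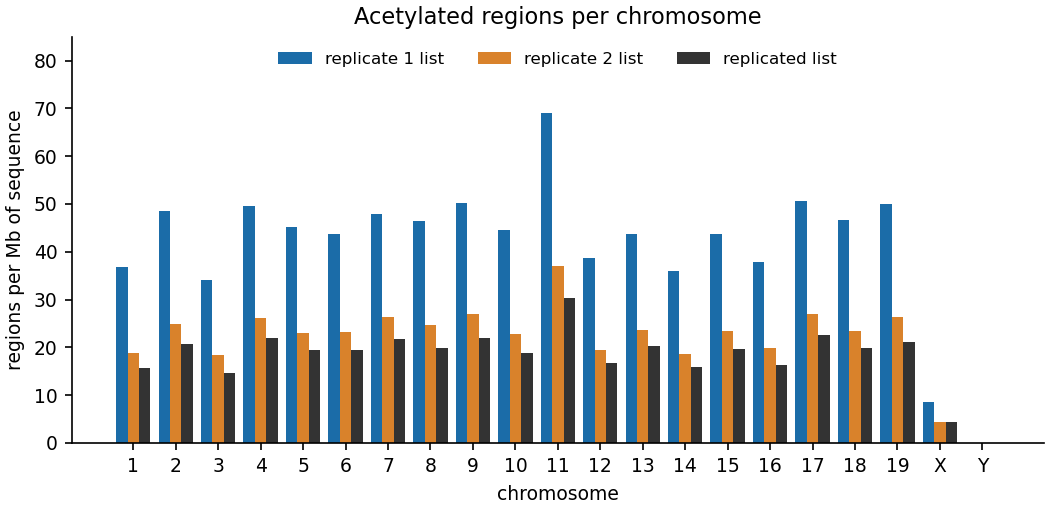
Acetylated regions per Mb (vertical axis) on each chromosome (horizontal axis) in replicate 1, replicate 2 and the replicated list. In the replicated list the X chromosome lies at 4.27 and the autosomes between 14.6 and 30.3.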

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

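The tests of sequencing depth, of gene density on the X chromosome and of X signal at matched fold thresholds were chosen only after the result was seen. The signal-over-background test, the repeat test and the test with the least fold were chosen before.

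Outside the chromosomes used in the report, 6 replicated regions lay on scaffolds with no chromosome position, some of them on scaffolds named for chromosomes 4 and X. The strongest had a fold of 26.8. No explanation was tested.

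Replicate 1's list held 109276 regions and replicate 2's 57342. At shared replicate 2 regions, each paired with its strongest partner in replicate 1, the fold was mostly higher in replicate 1. Deeper sequencing of replicate 1 stays open: its background pileup was 0.794 times that of replicate 2, but the pileup also scales with fragment length, which is not given in the sources used here. A candidate explanation is a higher signal over background in replicate 1: after its excess fold was divided by 1.95, the median ratio at shared strong regions, and its p recomputed on replicate 2's background, 66987 regions would reach replicate 2's least p, 1.17 times replicate 2's number. The 1.95 came from these same lists and from a pairing that favours replicate 1, so the division itself draws the number toward replicate 2's. All regions were also put on replicate 2's background pileup, which matched 52.1% of replicate 2 peaks. The count therefore cannot show that the signal over background was higher. Whether the antibody step, the technical replicates that were combined, or the embryo pools differed stays open too. No biological explanation was tested, because the design has 1 group.

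The X chromosome had 0.217 times the regions per Mb of the autosomes. Fewer genes on the X do not account for it, since regions per protein-coding gene were 0.736 on the X and 2.26 on autosomes (ratio 0.326), and neither does repeat sequence, since the ratio outside repeats was 0.272. Whether X regions carry a reduced signal (autosomal signal above background divided by 2) stays open: at 5 of 6 pairs of thresholds X regions were 0.791 (X fold 4, autosomal fold 7) to 0.857 times as dense (X fold 10, autosomal fold 19), above the gene density ratio of 0.668, but with X fold 3 and autosomal fold 5 the ratio was 0.608, below it. A test with the least fold of the X as threshold gave 0.247 and decided nothing, because the division removed few autosomal regions. A lone active X chromosome in each cell and fewer mapped reads on the X, which were not analysed here, both stay open, and the design tested no biological explanation.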

How the results depend on the processing

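Of the alternatives, the use of replicated regions that touch a peak of both replicates was chosen only after the data were seen. Of 134 alternatives of the main results, 98 kept their direction and side of the threshold or stayed within the spread, and so did 121 of 136 for single gene lists at promoters, 113 of 119 for domains and 120 of 168 for motifs. The 134 include the overlap with peaks left unmerged, which could not differ from the main result because 0 peaks overlapped within a list. Shared percentages stayed above shuffled ones in every alternative, from 15.9 to 50.7% for replicate 1 and 30.3 to 93.6% for replicate 2. No paired analysis was possible, because there is 1 group, and the unknown depth limits every count of regions. For the changes below the cause was not tested.

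With the pooled list, introns held 50.8% of regions (above the shuffled share), the HoxA flank had 1.99 times the shuffled bases, 1 gene list was lower in its domains, clusters numbered 33975, 10 of the top 20 were shared, 3 motifs were depleted and the X ratio was 0.167. Leaving out a replicate gave 43.5 to 50.7% in introns, 1.83 to 2.65 times at HoxA, 0 to 1 lists lower in domains, 24468 to 32831 clusters, 10 to 15 shared top clusters, 3 motifs depleted either way and an X ratio of 0.181 to 0.188. At fold 4 or more, rho was 0.690, introns held 34.2% (below it), 1 motif was depleted and the X ratio was 0.290. With regions touching both replicates' peaks, introns held 38.7% (below it), 5 motifs were enriched, 2 were depleted and the X ratio was 0.236. Rho was 0.610 with −log10 p and 0.796 with a reciprocal overlap. Introns held 44.9% (above) with a promoter window of 500 bp and 41.3% (below) with 2 kb. Against genes of like CpG content 3 lists were lower at promoters, and with a window of 100 kb 1 list was lower. Joining within 5 kb kept 12 of the top 20 clusters and within 20 kb 9. Windows of 200 bp on either side and distal regions over 5 kb from a TSS each gave 1 depleted motif. Dinucleotide shuffling gave 5, and turned the direction of AP-1 to 0.794, HOX13 to 1.53 and LEF/TCF to 0.906.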

Other observations

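The long noncoding RNA genes and the imprinted genes were chosen after the clusters were seen, and so was the test with 1 imprinted gene per locus. The first test of imprinted genes was chosen before its own result was seen.

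Several long noncoding RNA genes had acetylated promoters. Of 12 known genes picked by hand, 10 had a promoter region. In the whole lincRNA class, to which 8 of the 12 belong, 874 of 5854 genes (14.9%) had one, so the picked genes are not typical of it. Malat1 (fold 29.6, and 44.4 and 12.9 in the replicates) and Neat1 (18.5), abundant nuclear RNAs, were among the strongest. H19, a growth-restraining imprinted RNA (chromosome 7, 142575529 to 142578143), had a fold of 18.7 and lies inside the cluster with most acetylated bases. Hottip, transcribed from the distal end of HoxA, had 18, and Hand2os1 18.6, but in the replicated list these are also the promoter folds of their coding neighbours Hoxa13 and Hand2. In replicate 2's list Hottip (8.38) and Hoxa13 (10.9) differed, and Hand2os1 had the value of Hand2 in both replicates' lists. Hotair in HoxC (3.35) and Pantr1 (3.76) were weak and not found in replicate 2's list. Snhg1 had 17.6, Gas5 11.1 and Meg3 5.88, and Miat and Sox2ot had none.

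The strongest distal regions, also chosen after their values were seen, lay in Bicral (chromosome 17, 46855359 to 46859416; fold 50.5), near Tex44 (chromosome 1, 86440783 to 86444554; 41.0), near Zfp869 (36.1), and in Ncor2 and Zfhx3 (34.6 each). A region of 4032 bp between genes, 54.5 kb from the TSS of Col1a1 (chromosome 11, 94880314 to 94884345), had a fold of 33.3. A region near Nedd4 (chromosome 9, 72638990 to 72642324; 34.0) had the homeodomain site TAATTA near its summit, in the sequence ATACTGAACAGATAATTAGATGCACAAGAA. The other 9 of the 10 strongest distal regions had no match to any of the 21 motifs within 100 bp of the summit. The share of all distal regions without a match was not counted, so whether these 9 are unusual cannot be told.

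Of the 20 clusters with most acetylated bases, 3 lay within 200 kb of imprinted genes, Igf2 at the first, Mest and Copg2 at the second and Grb10 near the one at Fignl1. This prompted the list of 40 imprinted genes, so it is not tested here, and the hypothesis is that imprinted genes as a class may have more distal acetylated sequence than other genes. The 36 imprinted genes farther away had a median of 2990 bases against 591 in random lists matched on domain length, at percentile 99.9 (permutation p = 0.00220). Neighbouring imprinted genes share regions, however, and with 1 gene for each of their 17 loci the first by name gave a median of 869 against 368 (permutation p = 0.448). Of 20 random choices per locus, 10 passed the bound set for the test (permutation p from 0.00300 to 0.718), so the excess rests on which genes stand for a locus and the hypothesis stays open.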
